A study of Mus musculus with 12 samples.

How the data were processed

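RNA from primary mouse microglia was measured on 12 Affymetrix Mouse Gene 1.0 ST arrays, one sample per array. The deposited values are log2 signals per probe set, made by the authors with Affymetrix Expression Console 1.1 and RMA, per the submitters' processing notes. RMA corrects the background, normalizes the arrays by quantiles and summarises the probes of a probe set. The values ran from 1.25 to 14.5, and the array medians from 6.30 to 6.40. No scanner files were used here, so background correction and summarisation were kept as the authors made them, and differences of overall RNA content between arrays cannot be seen after this normalization.

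Groups were taken from the sample titles, read with the series' own key: wild-type control, wild-type ischemia, knockout-labelled control and knockout-labelled ischemia, 3 arrays each. The labels conflict for the wild-type ischemia arrays, whose source name reads as control conditions although their title and the series key put them under hypoxia; the titles were followed. The extraction protocol names myocytes, while all other labels name microglia. The replicate number came from the title. No 2 arrays held identical values, and the highest correlation between 2 arrays was 0.992.

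Of 35557 probe sets, 21789 had 1 gene symbol in the platform annotation given here, 1621 had several and were not named, and 12147 were not listed. Symbols were updated through Entrez identifiers to a current gene table (GRCm38.p6), which matched 21698 of the 21789. The brightest probe set by mean signal stood for each gene (999 symbols had several). Genes with a mean at or below the 30th percentile of all probe sets (5.36 log2) were left out, which left 15273 genes. The build behind the array annotation is not given in the sources used here, so no coordinates are printed and the gene table served only for names, chromosomes and the order of genes.

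A linear model with 1 mean per group was fitted over all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), which gives each comparison the same estimate of spread. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Comparisons were ischemia against control in each genotype, knockout-labelled against wild type in each condition, and the difference of the 2 ischemia effects. Gene lists (26) were tested with camera at a preset correlation of 0.01, adjusted over the 26 lists; camera with an estimated correlation and fry, whose directional p tests whether a list's genes move on balance one way, were run beside it. Changes are differences of log2 signal, and a fold is 2 to that power.

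Replicate numbers were checked for pairing by correlating deviations from the group means over genes. Same-numbered arrays correlated at 0.48, 0.73 and 0.48 between wild-type control and ischemia, and at 0.36, 0.32 and 0.49 in the knockout-labelled arrays, each above a minimum of 0.1. Differently numbered arrays correlated at -0.62 to 0.40 in the wild type and -0.44 to 0.22 in the knockout-labelled arrays. Some of these also passed 0.1, but each lay below every same-numbered value of its genotype. Within a genotype the numbers were thus taken to pair the samples, which rests on the data because the labels do not say what a number stands for. Between genotypes they were not, because not all same-numbered values passed 0.1 (-0.33 to 0.15 in control cells, -0.15 to 0.33 after ischemia). The paired fit has 1 block level for each genotype and number and was chosen after the values were seen; the fit with a 3-level replicate block over all arrays was set beforehand.

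The groups, comparisons, tests, gene lists, alternative settings and the rule for named genes were set before the data were examined. The rule takes, among called genes whose groups do not overlap, the 8 largest rises and 8 largest falls, then Tlr4 and up to 4 members with the largest change of each list described; where fewer pass, the genes with the smallest p fill up to 4. The named genes are a selection from those this rule gives, made after their values were seen. The steps were tested on simulated data of 15273 genes with known changes. Simulated as the wild-type ischemia comparison with shared cultures, 85.1% of genes changed by 1 on the log2 scale were recovered without the block and 98.5% with it, and 44.8% and 82.1% of those changed by 0.5, with 0 and 12 false calls. Simulated with independent arrays, the block lowered recovery, from 89.6% to 77.6% at 1 and from 41.8% to 23.9% at 0.5, with 10 false calls without it and 8 with it. The shared cultures were simulated with a stronger link than most same-numbered pairs showed, and with genes drawn independently. For the genotype comparisons with shared cultures, the fit without the block made 18 false calls of 160 in control cells and 11 of 160 after ischemia.

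Alternatives were the samples in the fit, the replicate block, the filter on dim probe sets, quantile normalization or median centring of the deposited values, eBayes with trend and robust settings, array weights, the mean of all probe sets per gene, each array left out in turn and, for lists, the other list tests. Added after the values were seen were the block within genotype, the fits without both wild-type arrays numbered 2, the Y-linked level as a covariate, and the means of same-numbered pairs for Tlr4. Signal over background was not measured here, because no background values were used.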

Results

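The series measured RNA levels in primary mouse microglia, the resident macrophages of the brain, on 12 Affymetrix Mouse Gene 1.0 ST arrays. Cells from wild-type mice and from mice labelled as lacking Tlr4, the receptor for bacterial lipopolysaccharide, were held for 24 h without normal oxygen and glucose (ischemia) or under control conditions. All cells then had 24 h of normal oxygen and glucose (reperfusion), so every array shows the state after recovery. Each of the 4 groups held 3 arrays, numbered 1 to 3. The deposited log2 RMA values of 35557 probe sets gave 15273 genes for testing. Arrays of a group correlated with each other at 0.976 or more over all probe sets, and the number of arrays limits the precision. The labels do not say whether the arrays of a group came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

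The signal of Tlr4 itself did not differ detectably between the arrays labelled as knockout and the wild-type arrays. Its 1 probe set read 8.71 ± 0.22 (SD, n = 6) in the knockout-labelled arrays and 8.74 ± 0.18 (SD, n = 6) in the wild-type arrays. Its mean was above that of 81.1% of probe sets and above the 5.36 log2 used to leave out dim genes. The difference of -0.02 on the log2 scale had p = 0.851 in a two-sided exact permutation test of 6 against 6 arrays, which takes the arrays as independent. Same-numbered arrays of a genotype deviate together, and with the mean of each such pair as 1 value (n = 3 a genotype, chosen after the values were seen) the 95% interval from limma was -0.36 to 0.31 (two-sided exact permutation test of 3 against 3 pair means, p = 0.900), so a difference of that size in either direction is not excluded. A probe set outside the altered part of the gene checks nothing, and the labels do not describe the alteration. The 6 arrays are therefore called knockout-labelled throughout, and every direction below rests on those labels.

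The first comparison asked what ischemia and reperfusion did to wild-type microglia. Interferon-stimulated genes, the antiviral program that type I interferon turns on, were higher in all 43 measured members, with a median change of 1.00 on the log2 scale. AW112010 rose 3.59-fold and Cfb, complement factor B, rose 3.13-fold. MHC and antigen-processing genes were higher by a median of 0.55 over 15 members, and cell division genes were lower by a median of -0.31 over 30 members. All 3 same-numbered pairs of arrays had a higher mean of the interferon list after ischemia, by 1.42, 1.05 and 0.72.

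Among single genes, limma called 2 higher and 0 lower at an adjusted p under 0.05, while 2241 had an unadjusted p under 0.05. The 2 called genes were AW112010 (log2 change 1.85, SE 0.18, adjusted p = 0.00406) and Cfb (1.65, SE 0.22, adjusted p = 0.0475). Same-numbered arrays deviated together within each genotype, so the change was also fitted with the replicate number as a block within genotype (the paired fit, chosen after the values were seen). The paired fit in limma called 570 genes, 457 higher and 113 lower. The 2 groups did not overlap for 21.7% of genes, where chance gives 10% for 3 arrays against 3.

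In the interferon list, 0 of 43 members passed without the block over all genes tested and 11 adjusted over the list alone; 40 rose in the paired fit, and 42 adjusted over the list alone. Ifit2 changed by 2.23 (SE 0.84, limma adjusted p = 0.290; paired fit 8.26e-05), Ifit1 by 1.80, and Irf7, the master regulator of type I interferon production, by 1.63 (SE 0.61, limma adjusted p = 0.287; paired fit 8.07e-05). Ifit3 changed by 2.09, with a paired-fit limma adjusted p = 0.00414. The paired fit takes 1 spread per gene over both genotypes. The pair changes of the list mean had an SD of 0.35 in the wild type and 0.075 in the knockout-labelled arrays. Its p-values and counts for these genes may thus overstate the evidence from the wild-type pairs alone. The list as a whole was shifted upward (camera adjusted p = 1.82e-18; adjusted p = 0.388 with an estimated correlation). In the paired fit that call was also lost (adjusted p = 0.188 with an estimated correlation), while fry gave an adjusted p = 0.0179 in the paired fit and 0.142 without the block. The list median was 0.59 without wild-type ischemia array 2. Wild-type arrays numbered 2 had the highest interferon means in both conditions, at 9.19 in control cells and 10.24 after ischemia. Those arrays also had the highest means of the monocyte and border-associated macrophage markers, at 8.28 and 8.17, against 7.30 to 7.58 in the other wild-type arrays.

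Of 15 antigen-presentation genes, 10 rose in the paired fit of limma, and 7 passed without the block when adjusted over the list alone. The MHC class II genes H2-Aa and H2-Ab1 changed by 1.13 and 0.92, the invariant chain Cd74 by 0.84, and the peptide transporter Tap1 by 0.81 (camera adjusted p = 1.95e-06 for the list; adjusted p = 0.244 with an estimated correlation). Among 29 Toll-like receptor pathway genes, 28 were higher and 5 rose in the paired fit, among them the endosomal receptors Tlr3 (0.79) and Tlr8 (0.52). Ly96, the co-receptor of Tlr4, was 1.05 higher without passing (limma paired-fit adjusted p = 0.0548). That list had a camera adjusted p = 0.000162 (adjusted p = 0.165 with an estimated correlation). From the inflammatory list, the chemokine gene Ccl5 and Acod1, which makes itaconate, rose by 1.57 and 0.81 in the paired fit, but the list was not called (median 0.05, camera adjusted p = 0.764). Of 19 disease-associated microglia genes, 3 rose in the paired fit: Cst7 (0.78), Cd52 (0.75) and Csf1 (0.60), with a camera adjusted p = 0.0264 for the list (adjusted p = 0.388 with an estimated correlation). That call was lost without wild-type control array 1, wild-type control array 3 or wild-type ischemia array 1 (camera adjusted p = 0.15, 0.0662 and 0.0655).

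Cell division genes were lower in 29 of 30 members, and 9 fell in the paired fit of limma. The proliferation marker Mki67 fell by 1.25 (block SE 0.15, limma paired-fit adjusted p = 0.000627), and Ccna2 (-1.14) and Top2a (-0.98) fell too. The list had a camera adjusted p = 1.12e-05 (adjusted p = 0.482 with an estimated correlation). The list mean changed by -0.26, -0.85 and -0.15 in pairs 1, 2 and 3, and the camera call was lost without wild-type control array 2 (median -0.038, adjusted p = 0.393), while the median was -0.48 to -0.51 without wild-type control array 1, wild-type control array 3 or wild-type ischemia array 2. NRF2 antioxidant genes were lower in 16 of 19 members, and Nqo1 (-0.66), Srxn1 (-0.50) and catalase, Cat (-0.48), fell in the paired fit; the list had a camera adjusted p = 0.00702 (adjusted p = 0.482 with an estimated correlation). Its call was lost without wild-type control array 3 (-0.091, camera adjusted p = 0.125) or wild-type ischemia array 2 (-0.0084, adjusted p = 0.309), and its median was -0.29, -0.21 and -0.34 without wild-type control array 2, wild-type ischemia array 1 and wild-type ischemia array 3. All 28 mitochondrial respiratory chain genes were higher (median 0.22), 2 rose in the paired fit, one of them Cycs by 0.46, and the list had a camera adjusted p = 1.63e-06 (adjusted p = 0.388 with an estimated correlation). The mean of that list changed by 0.32, 0.049 and 0.32 in pairs 1, 2 and 3. All 20 cholesterol genes were higher (median 0.22) and Nsdhl rose by 0.54 in the paired fit. The camera adjusted p was 2.31e-05 (adjusted p = 0.388 with an estimated correlation), and the median was 0.13 without wild-type ischemia array 1. The list mean changed by 0.30, 0.084 and 0.35 in pairs 1, 2 and 3. The upper quartile of all signals was 8.24 to 8.25 in wild-type ischemia arrays and 8.13 to 8.17 in wild-type control arrays. A general rise of bright signals may thus enter these small changes, though quantile normalization kept the respiratory chain and cholesterol calls. Lysosome genes had a median of 0.08, a camera adjusted p = 0.0358 without the block (adjusted p = 0.482 with an estimated correlation) and were not called in the paired fit, nor without any of the wild-type arrays but ischemia array 2 (camera adjusted p from 0.0510 to 0.163).

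Some lists of markers of other cell types were called lower after the exposure, at low signals. Fibroblast and mural markers (median -0.23, camera adjusted p = 0.000831), neuron markers (-0.19, adjusted p = 0.0203) and astrocyte markers (-0.22, adjusted p = 0.0358) were lower after ischemia in wild-type arrays. With an estimated correlation these had adjusted p = 0.388, adjusted p = 0.388 and adjusted p = 0.417, and the astrocyte call was also lost in the paired fit. The astrocyte call was lost without wild-type control array 1, ischemia array 2 or ischemia array 3 (camera adjusted p = 0.15, 0.236 and 0.0734), and the neuron call without control array 1 (median -0.042), control array 2 or ischemia array 2 (median -0.12; adjusted p = 0.0726, 0.0532 and 0.0668). The fibroblast gene Col1a1 (-0.48) and the astrocyte gene Gfap (-0.35) did not pass. Mean signals in wild-type ischemia arrays were 5.84 for neuron, 6.52 for astrocyte and 6.51 for fibroblast and mural markers. The median wild-type change of all genes was -0.014 without the dim filter, 0.012 with it and 0.068 with the filter at the 50th percentile. Quantile normalization ended the neuron and astrocyte calls and kept the fibroblast one. A change of cell types was thus not separated from a shift of low signals. Hypoxia-inducible factor targets (median 0.13, camera adjusted p = 0.185) and glycolytic enzymes (0.07, adjusted p = 0.149) were not called, though Egln3 and Higd1a rose by 0.39 and 0.38 in the paired fit of limma. The remaining lists were not called either: stress response genes had a median of 0.13, liver X receptor targets 0.07, p53 and cell death genes 0.07, homeostatic microglia genes 0.04 and endothelial markers 0.04. Medians below zero without a call were those of matrix enzymes (-0.02), alternative activation genes (-0.04), neutrophil markers (-0.05), lymphocyte markers (-0.07), oligodendrocyte markers (-0.10) and border-macrophage markers (-0.11). Without wild-type control array 2 limma called 79 genes, and without wild-type control array 3, wild-type ischemia array 1 or wild-type ischemia array 3 it called 1. AW112010 kept its call whichever wild-type array was left out, and Cfb lost it without wild-type control array 3 or any one wild-type ischemia array, with only the 6 wild-type arrays in the fit (limma adjusted p = 0.351) and after quantile normalization (adjusted p = 0.125).

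**Figure D1:**
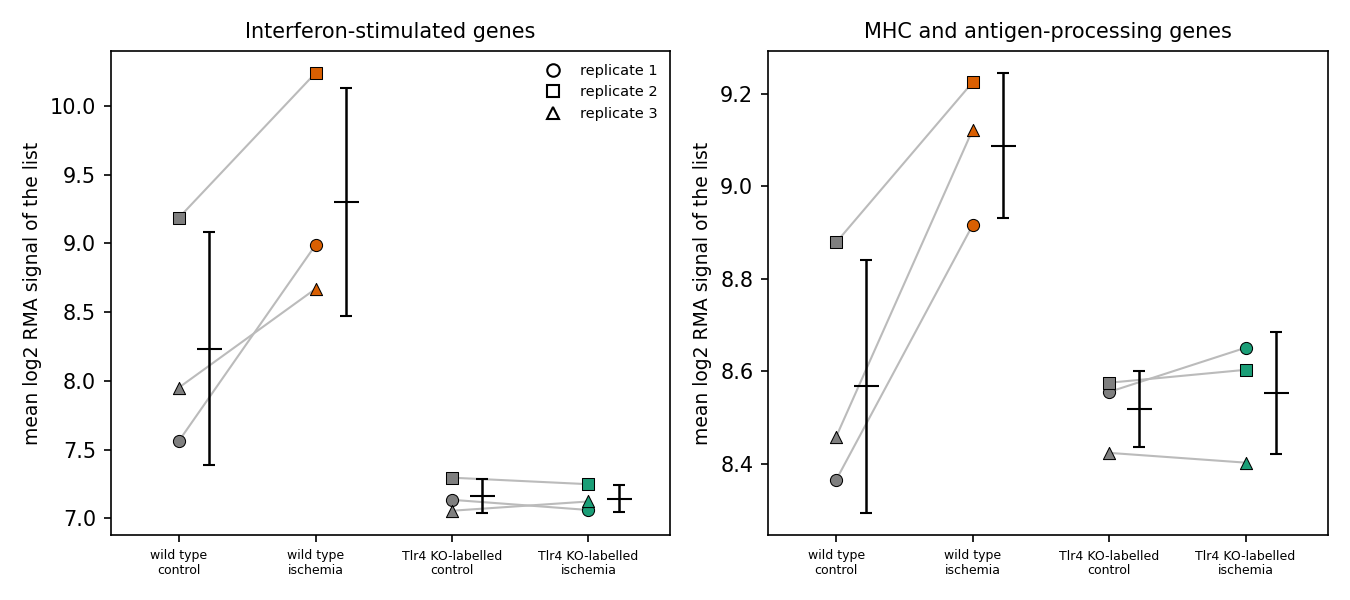
Mean log2 RMA signal of 43 interferon-stimulated genes (left) and 15 MHC and antigen-processing genes (right) per array, by group. Symbols give the replicate number, grey lines join same-numbered arrays, and black marks give the group mean ± SD (n = 3). All 3 wild-type pairs rise in both panels, while the interferon means of the 6 knockout-labelled arrays lie between 7.06 and 7.30.

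The second comparison put the same exposure to the knockout-labelled microglia. Here the interferon-stimulated genes were not called as a list (camera adjusted p = 0.900): 19 of 43 were higher and 24 lower, with a median of -0.04 and pair changes of -0.07, -0.05 and 0.07 in the list mean. Cholesterol genes were higher by a median of 0.23, glycolytic enzymes by 0.25, hypoxia-inducible factor targets by 0.17 and disease-associated microglia genes by 0.16. Homeostatic microglia genes had a median of -0.13.

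Limma called 0 genes (smallest adjusted p = 0.410), with 1334 at an unadjusted p under 0.05. The paired fit called 99, of which 82 were higher and 17 lower. Without the block, the smallest p-values for a rise belonged to Cd34 (1.04, block SE 0.12), Ralgapa2 (0.59), Tm4sf19 (0.62) and the interleukin-13 receptor chain Il13ra1 (0.81), all of which passed only in the paired fit (limma adjusted p = 0.00410, 0.0156, 0.0249 and 0.00535).

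Cholesterol genes were higher in 16 of 20 members, and Cyp51 and Idi1 rose by 0.62 and 0.55 in the paired fit of limma; 8 passed in the paired fit adjusted over the list alone. That list had a camera adjusted p = 0.000140 (adjusted p = 0.527 with an estimated correlation). Of 26 hypoxia-inducible factor targets, 20 were higher and 0 passed over all genes; adjusted over the list alone in the paired fit, 11 rose and 2 fell. The values were 0.48 for Pdk1, which turns pyruvate away from mitochondria, 0.42 for Bnip3 and -0.46 for Ndrg1 (camera adjusted p = 0.00736 for the list; adjusted p = 0.304 with an estimated correlation). Glycolytic enzymes were higher in 13 of 15 members, with Pgk1 at 0.37 and Hk2 at 0.33, and 0 passed over all genes (camera adjusted p = 0.00775; adjusted p = 0.196 with an estimated correlation). Csf1 and Cst7 of the disease-associated list rose by 0.77 and 0.48 in the paired fit (camera adjusted p = 0.0182 for the list; adjusted p = 0.527 with an estimated correlation). Without knockout-labelled control array 1 only 1 list was called, and the hypoxia, glycolytic and disease-associated lists each had a camera adjusted p = 0.106. The disease-associated list was also lost without knockout-labelled control array 2 or ischemia array 1 (adjusted p = 0.0870 and 0.0608), and the glycolytic median was 0.16 without knockout-labelled control array 2.

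In the homeostatic list, Cx3cr1, the fractalkine receptor, and the complement genes C1qa and C1qb fell in the paired fit of limma, with changes of -0.61, -0.48 and -0.45; 6 of the 19 members fell and 1 rose adjusted over the list alone. Only the paired fit called this list (camera adjusted p = 0.00600; adjusted p = 0.565 with an estimated correlation). In the paired fit of limma the scavenger receptor gene Stab1 (-0.65) and the folate receptor gene Folr2 (-0.69) also fell, while Plaur, the urokinase receptor gene, and Pf4, platelet factor, rose by 0.63 and 0.58. Of the interferon genes, Samd9l (0.42) did not pass, nor did Ifit1 and Mx2, whose means after ischemia (4.85 and 4.51) lay below the 5.36 log2 used to leave out dim genes. No list of another cell type was called, and knockout-labelled control array 3 stood apart from the other arrays, with a median correlation of 0.976 with them against 0.982 or more for the rest. Without that array 8 lists were called.

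**Figure D2:**
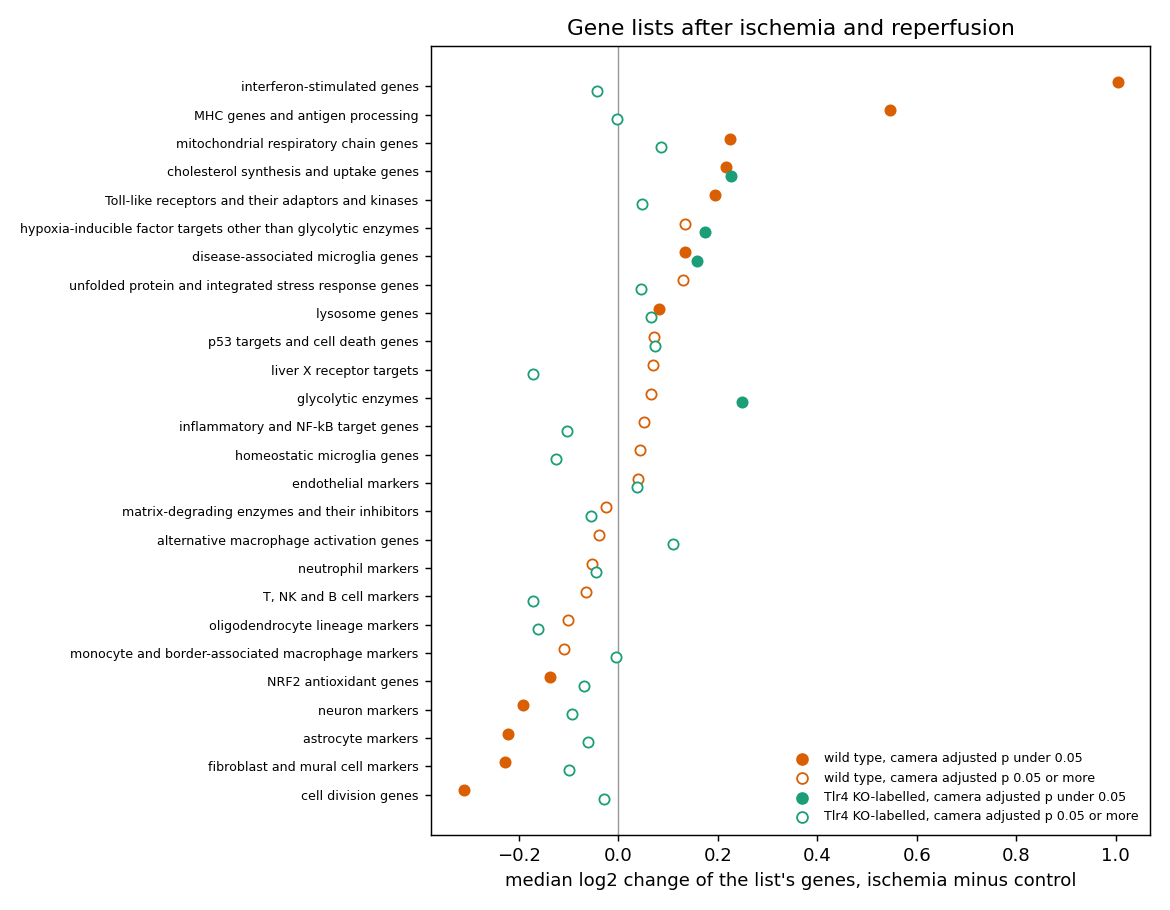
Median log2 change after ischemia and reperfusion (horizontal axis) of each of the 26 fixed gene lists, in wild-type and knockout-labelled arrays (3 arrays a group). Filled points had a camera adjusted p under 0.05 at a preset correlation; 0 of these calls held with an estimated correlation. The interferon list lies at 1.00 in the wild type and -0.04 in the knockout-labelled arrays.

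Across all 15273 genes, the ischemia effects of the 2 genotypes correlated at r = 0.477, a value across genes, which are not independent replicates. Of 643 genes called in either genotype by the paired fit, 82.1% changed in the same direction. In both genotypes 26 were called, all 26 in the same direction, where independent lists would share 2.58 in the same direction. Both calls of a gene use the same estimate of its spread, so the lists are not independent and 2.58 is only a rough mark.

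The third comparison asked what the genotype did in control cells. Inflammatory genes were lower as a list in the 3 knockout-labelled arrays than in the 3 wild-type arrays under every list test. Interferon-stimulated and Toll-like receptor pathway genes were called lower by camera only at the preset correlation (adjusted p = 0.620 and 0.265 with an estimated correlation). Lox, a collagen cross-linking enzyme, was 3.10-fold lower and Aoah, an enzyme that inactivates lipopolysaccharide, 3.58-fold lower. Cfb was 3.31-fold lower, Acod1 2.67-fold lower and the acute-phase gene Saa3 2.79-fold lower. Tmod1, an actin-capping protein gene, was 2.49-fold higher.

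Limma called 9 genes, 1 higher and 8 lower, with 1091 at an unadjusted p under 0.05. The groups of 9.89% of genes did not overlap, where chance gives 10%. The genes that fell were Lox (-1.63, SE 0.17, limma adjusted p = 0.00676), Aoah (-1.84, SE 0.22, adjusted p = 0.0112), Cfb (-1.73), Saa3 (-1.48), Acod1 (-1.41), Tgfbi (-0.97), the kinase gene Ikbke (-0.88) and Tlr2 (-0.76), the receptor for bacterial lipoproteins. Tmod1 rose by 1.31 (SE 0.16, limma adjusted p = 0.0112). Next in p among higher genes, without passing, were Tspan13 (0.81) and Asb10 (0.63).

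In the inflammatory list 29 of 32 members were lower, 2 fell over all genes and 8 adjusted over the list alone. Ccl5 (-2.58, limma adjusted p = 0.104) and Cxcl2 (-1.18) did not pass over all genes. This list kept its call under every list test (camera adjusted p = 6.91e-11, adjusted p = 0.0420 with an estimated correlation, fry adjusted p = 0.0149), and its median of -0.28 was -0.43 without wild-type control array 3. In the interferon list 41 of 43 members were lower (median -0.94), 0 fell over all genes and 22 adjusted over the list alone. Rtp4 (-3.33, SE 0.67), Irf7 (-2.19) and Oas3 (-2.01) had the limma adjusted p-values 0.176, 0.540 and 0.540. The interferon list had a camera adjusted p = 5.37e-25 (adjusted p = 0.620 with an estimated correlation), and its median was -0.56 without wild-type control array 2. The mean of 3 Y-linked genes was higher in the knockout-labelled arrays than in the wild-type arrays numbered 1 and 3, and with it as a covariate (chosen after the values were seen) the median was -2.06 and limma called 654 genes.

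The Toll-like receptor pathway list had a median of -0.10, with 19 of 29 members lower and 10 higher, and 2 genes, Tlr2 and Ikbke, falling over all genes and 3 adjusted over the list alone (camera adjusted p = 0.00769; adjusted p = 0.265 with an estimated correlation). Its call was lost without knockout-labelled control array 1 (camera adjusted p = 0.0986) or wild-type control array 2 (median -0.0043, adjusted p = 0.236), and its median was -0.19 without wild-type control array 1 and 0.014 with array weights. Cell division genes were lower in 28 of 30 members (median -0.35, camera adjusted p = 1.18e-06; adjusted p = 0.901 with an estimated correlation), with Bub1b at -0.76, Mki67 at -0.68 (0.11 with array weights) and Top2a at -0.94, none passing over all genes. Their mean was 8.04 in wild-type control array 2 against 7.01 and 6.89 in the other wild-type control arrays. Without array 2 that list was not called (median -0.019, camera adjusted p = 0.953), and without wild-type control array 1 or 3 its median was -0.57 or -0.53. Outside the called lists, the matrix protease Mmp14 (-1.66) and the death receptor Fas (-0.74) were lower and the disease-associated genes Trem2 (0.49) and Itgax (0.53) higher, and none passed. Limma called 0 genes without knockout-labelled control array 3 or without wild-type control array 3, 3 without knockout-labelled control array 1 and 23 without wild-type control array 2. It also called 0 when only the 6 control arrays entered the fit. With array weights the calls did not lean to lower genes, with 333 higher and 325 lower.

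The fourth comparison asked the same after ischemia and reperfusion (3 arrays a genotype). Interferon-stimulated genes were lower in the knockout-labelled arrays in all 43 members, with a median of -2.03 on the log2 scale. Rtp4 was 29.8-fold lower, Ccl5 22.8-fold, Irf7 15.4-fold and Oas3 11.8-fold lower. Ifit1 fell too (limma adjusted p = 0.0161), but its mean of 4.85 log2 in the knockout-labelled arrays lay below the 5.36 log2 used to leave out dim genes, so no fold is given. Cfb was 10.7-fold, the oligoadenylate synthetase-like gene Oasl2 8.68-fold and the antiviral gene Rsad2 8.16-fold lower. Inflammatory, Toll-like receptor pathway and antigen-presentation genes were lower as well.

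Limma called 109 genes, 99 lower and 10 higher, with 1276 at an unadjusted p under 0.05. The groups did not overlap for 16.5% of genes, where chance gives 10%. All 9 genes called in control cells were called again in the same direction, though same-numbered arrays of a genotype deviate together, so these comparisons are not independent. Of the 99 lower genes, 23 were interferon-list members. Falls on the log2 scale were -4.90 for Rtp4 (SE 0.67, limma adjusted p = 0.00574), -4.51 for Ccl5 (SE 0.45, adjusted p = 0.000615), -3.94 for Irf7 (SE 0.61, adjusted p = 0.0108) and -3.42 for Cfb (SE 0.22, adjusted p = 2.58e-05). Adjusted over the interferon list alone, 42 of 43 fell; Ifit3 (-3.86) did not pass over all genes (limma adjusted p = 0.120). The list had a camera adjusted p = 2.16e-67 (adjusted p = 0.0579 with an estimated correlation) and a fry adjusted p = 0.0122.

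Of 32 inflammatory genes, 5 fell over all genes and 13 adjusted over the list alone, among them Acod1 (-2.40), Saa3 (-1.63) and Lcn2 (-1.53), which binds bacterial siderophores (camera adjusted p = 1.37e-12, adjusted p = 0.0132 with an estimated correlation). In the Toll-like receptor pathway, Tlr2 (-1.14) and Ikbke (-1.21) fell and Tlr8 (-1.21) did not pass (camera adjusted p = 7.71e-10 for the list, adjusted p = 0.0114 with an estimated correlation). Of 15 antigen-presentation genes, 14 were lower, 1 fell over all genes and 8 adjusted over the list alone. The gene that fell was Tapbp, the peptide-loading factor tapasin (-0.81), while Tap1 (-1.33, limma adjusted p = 0.0535) and Psmb8 (-0.82) did not pass (camera adjusted p = 1.18e-10 for the list, adjusted p = 0.0430 with an estimated correlation). Homeostatic microglia genes had a median of -0.28 (camera adjusted p = 0.00737; adjusted p = 0.294 with an estimated correlation), with P2ry13 at -0.54, Aif1 at -1.55 and Cx3cr1 at -0.94, none passing over all genes, and were not called without wild-type ischemia array 2 (median -0.13, camera adjusted p = 0.279). The matrix protease gene Mmp14 fell by 2.37 (limma adjusted p = 0.00268).

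Higher in the knockout-labelled arrays were Tmod1 (1.43, SE 0.16, limma adjusted p = 0.00136), the progenitor and vascular marker Cd34 (1.16), Mn1 (0.82), Zfp462 (0.82), Gng10 (0.79), Ralgapa2 (0.58) and the proton-activated chloride channel Pacc1 (0.55). Tmod1, Zfp462 and Gng10 lie on chromosome 4, as Tlr4 does. Eif2s3y, a gene of the Y chromosome, rose 2.82-fold (SE 0.30 on the log2 scale, limma adjusted p = 0.0421). The mean of the Y-linked genes Kdm5d, Uty and Eif2s3y, the first 2 chosen after their values were seen, was 6.93 to 7.47 in the knockout-labelled arrays, 6.90 and 7.10 in the wild-type arrays numbered 2, and 5.68 to 6.16 in the other wild-type arrays, so this mean moves with the genotype. With it as a covariate the interferon median after ischemia was -3.20 and limma called 665 genes. Vegfa (0.42), Slc2a1 (0.39) and Adamts1 (0.86, and -0.015 with the Y-linked level as a covariate) were higher without passing. Limma called 25, 52 and 31 genes without knockout-labelled ischemia array 1, 2 or 3, and 63 without wild-type ischemia array 1. Without wild-type ischemia array 1 there were 8 called lists. With array weights limma called 420 genes higher and 522 lower.

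**Figure D3:**
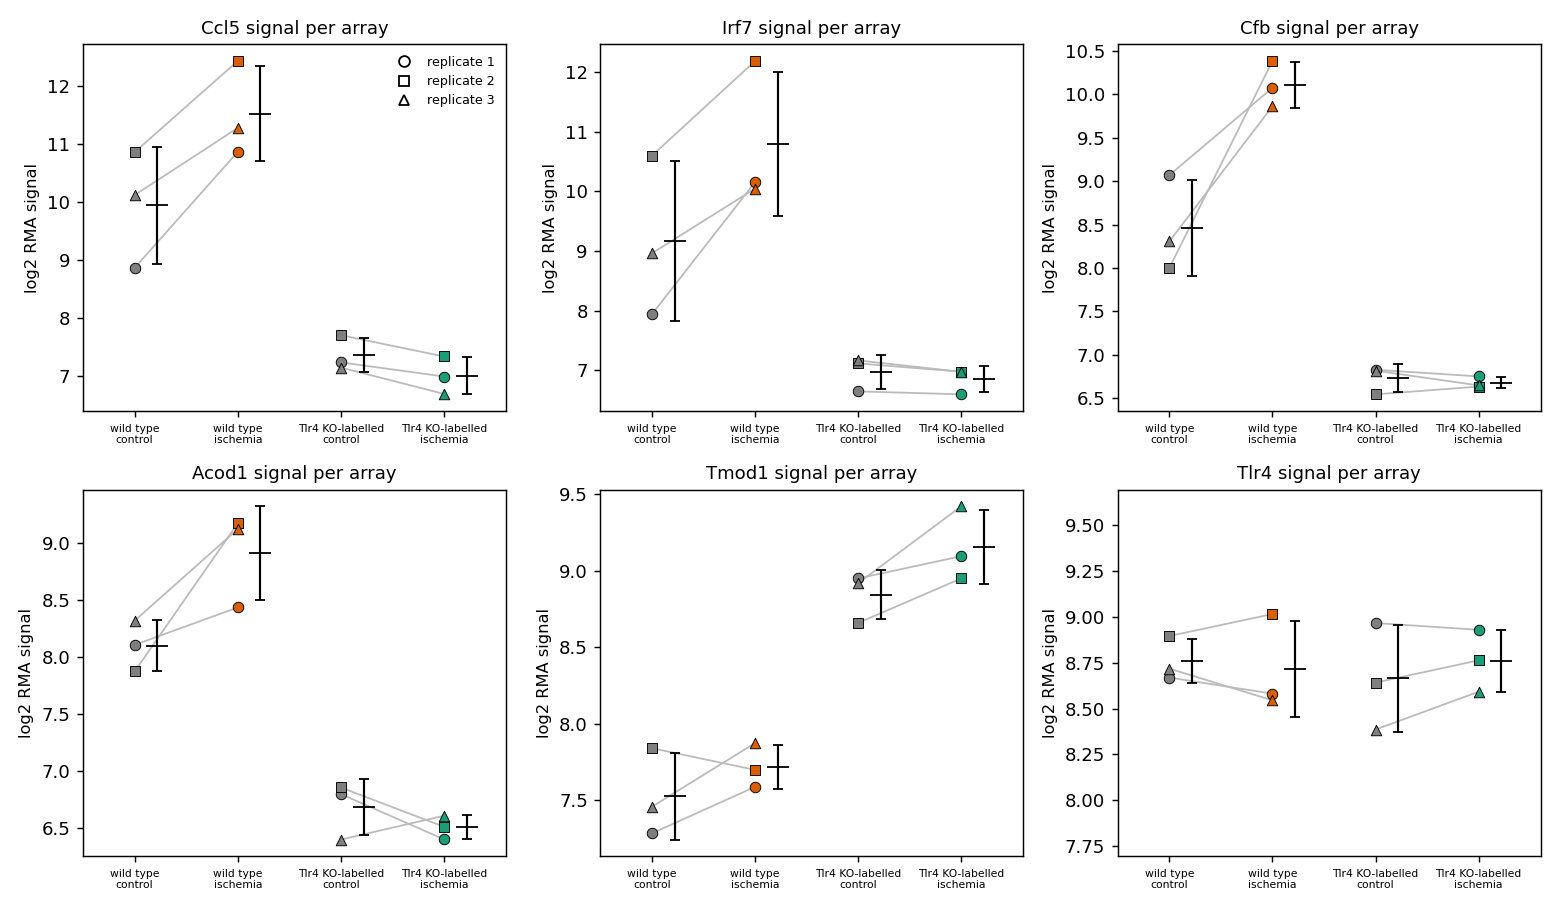
Log2 RMA signal per array of Ccl5, Irf7, Cfb, Acod1, Tmod1 and Tlr4 by group, with symbols for the replicate number, grey lines joining same-numbered arrays and black marks for the group mean ± SD (n = 3). Ccl5, Irf7, Cfb and Acod1 are lower in every knockout-labelled array than in any wild-type array after ischemia, Tmod1 is higher, and Tlr4 overlaps between the genotypes.

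The last comparison tested whether the ischemia effect itself differed between the genotypes. For the interferon-stimulated genes, all 43 differences (change in the knockout-labelled arrays minus change in the wild type) were below zero, with a median of -0.99. Camera called that list at the preset correlation but not with an estimated one (adjusted p = 0.549), and 0 members passed without the block. The median difference was -0.59 for antigen-presentation genes, -0.17 for Toll-like receptor pathway genes, -0.13 for respiratory chain genes, 0.29 for cell division genes and 0.17 for NRF2 antioxidant genes. These lists too were called only at the preset correlation (adjusted p = 0.153, 0.153, 0.718, 0.718 and 0.718 with an estimated one), and the cell division median was -0.021 without wild-type control array 2.

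Limma called 0 genes for this difference (smallest adjusted p = 1.00), with 443 at an unadjusted p under 0.05, and 1 gene without knockout-labelled control array 3 or without wild-type control array 1. The paired fit called 47, of which 2 were positive and 45 negative. Among them were AW112010 (-1.52, block SE 0.19, limma adjusted p = 0.00281), Cfb (-1.70), Ccl5 (-1.93), Rsad2 (-1.78), Tap1 (-0.93) and Psmb8 (-0.76). Ifit1 and Ifit2 passed too, but a knockout-labelled mean of each (4.85 after ischemia and 5.30 in control cells) lay below the 5.36 log2 used to leave out dim genes, so no size is given. Of the interferon list 0 members passed without the block; in the paired fit 19 did over all genes and 41 adjusted over the list alone, and of the 15 antigen-presentation genes 3 and 9 did. Tlr3 (-0.51) and C1qb (-0.66) did not pass, nor did Top2a (1.08), Ccna2 (0.99) and Trim80 (0.82), nor Ifit3 and Syt10, each with a group mean below that level (5.34 and 5.25). Trim80 and Syt10 were among the positive differences with the smallest p.

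The interferon list had a camera adjusted p = 1.67e-22 (adjusted p = 0.549 with an estimated correlation, 0.113 in the paired fit) and a fry adjusted p = 0.783 without the block and 0.0419 in the paired fit. Antigen presentation had 1.38e-07 (adjusted p = 0.153 with an estimated correlation) and the Toll-like receptor pathway 0.00154 (adjusted p = 0.153 with an estimated correlation). Cell division, respiratory chain and NRF2 genes had camera adjusted p-values of 0.000188, 0.00380 and 0.0352 (each adjusted p = 0.718 with an estimated correlation). The paired fit also called the homeostatic microglia list (median -0.17, camera adjusted p = 0.000453; adjusted p = 0.113 with an estimated correlation) and liver X receptor targets (-0.29, camera adjusted p = 0.00637; adjusted p = 0.432 with an estimated correlation). Without wild-type ischemia array 2 the interferon median was -0.53, the cell division median 0.48 and the NRF2 median 0.016, and without wild-type control array 2 they moved to -0.021 for cell division (camera adjusted p = 0.981), 0.25 for NRF2 and -0.23 for the respiratory chain. Without wild-type control array 3 the cell division median was 0.52, and the NRF2 (0.088) and respiratory chain (-0.052) calls were lost. The NRF2 call was also lost without knockout-labelled control array 1, knockout-labelled control array 2, knockout-labelled ischemia array 3 or wild-type ischemia array 2 (camera adjusted p = 0.308, 0.163, 0.394 and 0.717) and the respiratory chain call without knockout-labelled control array 1 (adjusted p = 0.0957). The NRF2 median was 0.26 without wild-type ischemia array 3, and the Toll-like receptor median -0.099 without wild-type control array 1.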

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

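All tests of explanations in this part were chosen after the result was seen, with 1 exception. The median absolute t of the 50 tested genes nearest to Tlr4 was set before. The results below stand here because a test of the difference itself called a different ischemia effect in the genotypes. Those calls came from camera at the preset correlation and from the paired fit. The fit without the block, set beforehand, called 0 genes for the difference. With camera at a preset correlation, the difference (knockout-labelled minus wild type, median log2) was -0.99 for interferon-stimulated genes, -0.59 for antigen-presentation genes, -0.17 for Toll-like receptor pathway genes and -0.13 for respiratory chain genes. It was 0.29 for cell division genes and 0.17 for NRF2 antioxidant genes, and 0 of these 6 calls held with an estimated correlation. With the replicate block within genotype, limma called 47 genes for the difference.

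The interferon-stimulated genes were higher after ischemia in the wild type and not in the knockout-labelled arrays. A single wild-type culture, number 2, is argued against as the source: without both of its arrays the median change was 1.07, against 1.00 with them, and the medians of the 3 pairs were 1.31, 0.93 and 0.70. If the wild-type ischemia arrays held control cells, as their source name reads, they would lack the changes of the other genotype; instead, the 99 genes changed in the knockout-labelled arrays moved by a median of 0.27 in their own direction, and 88, 84 and 86 of them did so in the 3 pairs. A role of Tlr4 itself, which the genotype labels name, was not tested and stays open.

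The second pattern is the set of genes lower or higher in the knockout-labelled arrays. A chromosome segment of another mouse strain around Tlr4, carried along when a mutant is bred, would put genotype differences near that gene; the 50 nearest tested genes had a median absolute limma t of 0.94, above the 95th percentile of 0.83 over 12979 windows, in line with such a segment for a part of the genes. On chromosome 4 lay 3 of the 9 higher genes with a known place and 6 of the 99 lower ones, against 967 of 14828 tested genes. Fisher's exact test, chosen after the calls were seen, gave a two-sided p = 0.0173 for the higher genes and p = 1 for the lower ones. Among the 50, only Tnfsf15 (-0.60), chosen after its value was seen, was called. A different mix of sexes in the cultures stays open as the source of these differences. The sex markers themselves did differ between the arrays. Xist, the transcript of the inactive X chromosome, read 10.89 to 11.05 in the wild-type arrays numbered 1 and 3. It read 10.29 and 10.36 in those numbered 2 and 8.98 to 10.40 in the knockout-labelled arrays. The Y-linked mean went the other way, with 6.93 to 7.47 in the knockout-labelled arrays. The called genes differed by a median of 1.43 in their own direction with the Y-linked level as a covariate and 1.25 without it. In the wild type that level was 6.90 and 7.10 in the arrays numbered 2 and 5.68 to 6.16 in the others. The covariate thus rests largely on the wild-type pair numbered 2, which also had the highest interferon means, and cannot decide this. That level itself moves with the genotype, and the covariate moved the interferon median further, from -0.94 to -2.06 in control cells and from -2.03 to -3.20 after ischemia, so the sizes of the genotype effects depend on it. The loss of Tlr4 itself, which the labels name, stays open beside the segment and the mix of sexes.

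The third pattern is that the Tlr4 signal was not lower in the knockout-labelled arrays. Of the 36 exchanges of 1 array of each genotype, 0 separated as many genes as the labels did (229, highest other 136). Each such exchange parts a same-numbered pair of each genotype. Those arrays deviate together, so parting them lowers the count whatever the genotype, and the count cannot decide about the labels. Such an exchange stays open, as do exchanges of more arrays. Of the 9 exchanges of a same-numbered pair of each genotype, 1 separated more genes than the labels, that of the wild-type pair 2 with the knockout-labelled pair 3 (384 genes); the Tlr4 difference would then be 0.29, so undoing it would not make Tlr4 lower. Among all 462 splits of the 12 arrays into 6 and 6, 8 separated at least as many genes, the labels included; 4 of the others exchange 2 arrays of each genotype and 3 exchange 3 arrays of each, among them the split into control and ischemia arrays (235 genes), which is the exposure and no exchange of labels. The highest gave 620, which points to a structure of the samples beyond genotype. A probe set outside the altered part of the gene stays open. The array has 1 probe set for Tlr4, the positions of its probes were not examined, and the labels do not describe the alteration. An exchange of the whole genotypes separates the same genes, so these counts cannot show it. It would only turn the sign of the Tlr4 difference of -0.024, so undoing it would not make the Tlr4 mean lower. The interval from limma on the pair means (-0.36 to 0.31) would turn as well, so a small fall is not excluded.

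For the difference between genotypes without the block, chance is not excluded: 56 of 100 drawn splits shifted as many lists as the real 6 (highest other 14). These splits ignore the pairs, so differences between same-numbered pairs enter their counts. The count of genes decides nothing here, since any split reaches the real 0 (highest other 3). With whole pairs exchanged between the genotypes and fitted as blocks, the 10 splits were too few for a share under 0.05: 1 of 10 called as many genes as the real 47 (highest other 0) and 2 of 10 shifted as many lists as the real 8 (highest other 11). Turning the exposure labels within pairs decides nothing about the difference, because turning pairs of 1 genotype leaves the ischemia effect of the other in place. Of the 32 ways, 3 called as many genes as the real 47, the real one included; the other two (1904 and 61 genes) turn knockout-labelled pairs only, and the 24 that turn a wild-type pair called 0.

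The other splits were too few for a share under 0.05. For the wild-type ischemia effect 4 of 10 splits called as many genes as the real 2 (highest other 10) and 1 of 10 shifted as many lists as the real 12 (highest other 11). For the knockout-labelled arrays 2 of 10 shifted as many lists as the real 4 (highest other 6), while the real 0 genes (highest other 2) are reached by any split and decide nothing. For the genotype effect in control cells the counts were 1 of 10 for 9 genes (highest other 0) and 6 of 10 for 4 lists (highest other 10). After ischemia they were 1 of 10 for 109 genes (highest other 0) and 7 of 10 for 5 lists (highest other 13). Among the 4 splits that part all pairs, fitted with the pairs as blocks, 1 of 4 called as many as the real 570 in the wild type (highest other 0), and 1 of 4 as many as the real 99 in the knockout-labelled arrays (highest other 0).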

How the results depend on the processing

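The replicate block within genotype, the fits without both wild-type arrays numbered 2, the Y-linked covariate and the means of same-numbered pairs for Tlr4 (-0.024) were chosen after the values were seen; the other settings were set beforehand. For 124 values of named genes there were 2242 alternative values. Of these, 1936 kept direction and call, 125 lost the call, 179 gained one and 2 reversed. A value not called in the main fit could not lose a call and counted as kept while it stayed uncalled. Of the 125 losses, 71 were for genotype after ischemia, 48 for genotype in control cells and 6 for ischemia in the wild type. For 31 called lists, 528 of 639 kept direction and call, 109 lost the call and 2 reversed. The median log2 change of all genes was at most 0.072 in absolute size in every setting and comparison. Unless said below, the cause was not tested. Signal over background was not measured, so what dim signals limit is known only through the filter.

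With the replicate block within genotype, which removes the differences between same-numbered pairs, limma called 570 genes for ischemia in the wild type (2 without it), 99 in the knockout-labelled arrays (0) and 47 for the difference between genotypes (0). The 3-level replicate block, whose numbers did not pair the genotypes, gave 3 and 1 for ischemia, 31 for genotype in control cells (9), 236 after ischemia (109) and 0 for the difference. Not every array correlated best with its own number across genotypes. Beyond the calls given with the results, the block within genotype changed no other list call.

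Without both wild-type arrays numbered 2, limma called 80 genes for ischemia in the wild type, 100 for genotype in control cells (38 higher, 62 lower), 295 after ischemia and 1 for the difference. With the replicate block within genotype as well, it called 488 for ischemia in the wild type, 100 in the knockout-labelled arrays and 30 for the difference. Array weights, from 0.28 (knockout-labelled control array 3) to 6.11 (knockout-labelled control array 2), gave 1025, 3157, 658, 942 and 1 genes for ischemia in the wild type, ischemia in the knockout-labelled arrays, genotype in control cells, genotype after ischemia and the difference; 2 lists in control cells; a correlation of 0.383 between ischemia effects (0.477); and reversed values for the Toll-like receptor list (0.014) and Mki67 (0.11) in control cells. The Y-linked covariate gave 654 genes and 10 lists for genotype in control cells, 665 genes and 12 lists after ischemia, interferon medians of -2.06 (-0.94) and -3.20 (-2.03), and -0.015 for Adamts1 after ischemia.

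Fitting only the groups compared gave 1 gene for ischemia in the wild type and 0 for genotype in control cells, with fewer arrays behind the spread. Quantile normalization gave 1 gene and 8 lists (12) for ischemia in the wild type, without the lysosome, disease-associated, astrocyte and neuron lists, 2 lists in the knockout-labelled arrays (4), without the glycolytic and disease-associated ones, and a Tlr4 difference of 0.020. The dim filter at the 50th percentile also gave 8 lists for ischemia in the wild type: the lysosome and disease-associated calls were lost, and the astrocyte and neuron lists had too few members left. It also ended the disease-associated call in the knockout-labelled arrays. Median centring gave 8 lists for genotype after ischemia. Camera with an estimated correlation called 0, 0, 1, 3 and 0 lists in the order above (12, 4, 4, 5 and 6 at the preset), and fry called 3, 1, 1, 4 and 0.

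With each array left out in turn, genes called ranged from 1 to 79 for ischemia in the wild type, from 0 to 23 for genotype in control cells, from 25 to 95 after ischemia and from 0 to 1 for the difference. Lists called ranged from 1 to 8 for ischemia in the knockout-labelled arrays and from 5 to 8 for genotype after ischemia. The correlation of ischemia effects ranged from 0.349 to 0.532, the Tlr4 difference from -0.075 to 0.041, the interferon median in the knockout-labelled arrays from -0.068 to 0.022, and the cell division difference from -0.021 to 0.52. Which array moved each count most is given with the results.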

Other observations

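The paired fit used in this part was chosen after the values were seen, as were the genes, which passed limma in that fit in both genotypes. Called in both genotypes were 26 genes, all of which changed in the same direction in the 2 genotypes. Slco4a1, an organic anion transporter gene, fell most, with -1.22 in the wild type and -1.08 in the knockout-labelled arrays. The paired immunoglobulin-like receptor genes Pilra (1.02 and 1.21) and Pilrb1 (0.76 and 0.73) rose, as did Nes (0.74 and 0.84), which encodes the filament protein nestin. Myeloid surface and chemokine genes were among them: the costimulatory gene Cd86 rose by 1.04 and 0.58, Slamf9 by 1.03 and 0.57, the chemokine receptor gene Ccr1 by 0.52 and 0.64 and Ccl9 by 0.43 and 0.66. Hilpda, a lipid droplet gene that hypoxia induces, rose by 0.39 and 0.58, and the vascular endothelial growth factor receptor gene Flt1 by 0.42 and 0.55. Of the macrophage genes, Stab1 (-0.53 and -0.65) and Folr2 (-0.58 and -0.69) fell and Pf4 (0.70 and 0.58) rose.

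The wild-type arrays numbered 2 stood apart in several gene groups. Their means of the homeostatic microglia list were 9.41 in control cells and 9.44 after ischemia, against 8.84 to 9.04 in the other wild-type arrays. Their means of the cell division list were 8.04 and 7.19, against 6.73 to 7.01. Xist had a log2 signal of 8.98 or more in all 12 arrays. The mean of the Y-linked genes was 5.68 to 6.16 in the wild-type arrays numbered 1 and 3. Eif2s3y read 5.44 in wild-type control array 1, near the 5.36 log2 used to leave out dim genes. A signal from male cells is thus not shown in those wild-type arrays.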
